A study of Homo sapiens with 6 samples.

How the data were processed

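RNA was measured in 6 libraries of THP-1 cells, 3 transduced with shRNA against CHD4 and 3 with negative control vectors, 72 h after transduction. The number and sequences of the shRNAs are not given in the sources used here. Per the labels' protocols, total RNA was made into strand-specific libraries with the TotalScript kit. The authors deposited whole-number counts per gene for all libraries in a single table, with Entrez gene IDs, coordinates and summed exon lengths, made with featureCounts 1.5.1 per the submitters' processing notes. The aligner and its version, the genome build, the annotation release, and the strand and multi-mapping settings are not given in the sources used here. Genes whose exons overlap others, and families with processed pseudogenes, may therefore hold reads of their neighbours or copies. Per the file headers the columns name aligned files, and each was matched to its sample by the label in its name.

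The table holds 27046 genes, and 26911 were matched to a symbol by Entrez ID in RefSeq's gene table for GRCh38.p14. The 135 others took at most 0.0413% of a library's counts and were kept. Of 25730 genes with a single location, 99.9% overlapped the same gene in that assembly, but the build is not named, so only the table's own coordinates are given. Of 980 list symbols, 19 matched no gene.

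Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with default settings (minimum count 10, minimum total 15), libraries were scaled by TMM, and the group effect was tested with robust quasi-likelihood fits. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are CHD4 shRNA minus control, and SE is the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled. SDs are over 3 libraries. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Within each group the replicates differed by more than sampling noise (chi-square per degree of freedom 3.44 to 13.9 over genes with at least 20 counts), so all 6 were used. The 3 against 3 design makes 10 splits, so a permutation of libraries cannot go below a p of 0.1.

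The depth ranged from 4939703 to 16511250 counts per library. Counts were simulated at the control means, the real depths and the fitted dispersion trend, with 200 genes changed. Among 11867 genes tested, the same test recovered 67.2% of genes changed by 1.5-fold, 89.4% of those changed by 2-fold and 100% of those changed by 4-fold. Of 174 calls, 9 were false (5.17%). The simulation changed far fewer genes than the 6751 called in the real comparison, so these shares may not hold for the real data. A gene with 3 or fewer counts over a group is given as a ratio with an exact binomial interval in place of a fitted fold.

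Before the data were examined, 25 gene lists were written from textbook knowledge: NuRD subunits, MYC targets, ribosomal proteins, DNA replication and G1/S, mitosis and G2/M, p53 targets, double-strand break repair, monocyte and macrophage markers, neutrophil granule genes, MLL fusion targets and stem cell genes, interferon response, NF-kB and inflammatory genes, BCL2 family and caspases, unfolded protein and ATF4 response, cholesterol synthesis, glycolysis and hypoxia, nuclear genes of the respiratory chain, the mitochondrial genome, immediate early and heat shock genes, erythroid and megakaryocyte markers, lymphoid markers, epithelial and packaging cell markers, fibroblast and endothelial markers, germline genes, and chromatin and Polycomb genes. The 22 lists with at least 5 measured genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Of these, 8 passed, 5 lower and 3 higher. With an estimated correlation 0 passed, and 6 had an unadjusted p under 0.05. With fry, which does not compare a list with other genes, 15 passed.

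Genes were named by a rule also set before the data were examined: CHD4 and MYC; the 8 largest rises and 8 largest falls past the threshold among protein-coding genes with a mean of at least 5 CPM and no overlap between the groups; for each list the 2 members with the smallest adjusted p in the direction most of its called members took, both directions if equal; and measured NuRD subunits as values. Other names were chosen after their values were seen, and the text says so. Some members of the lists are counted but not reported by name here. For named genes, overlap with other genes' exons was read from the table's coordinates and the reference.

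Alternatives were other scalings (DESeq2 size factors, total count, upper quartile), other tests (DESeq2 1.42.0, limma-voom, edgeR without robust estimation), no low-count filter or a mean of 5 CPM, a threshold of 0.01, a test against a fold of 1.5, the replicate number as a block, mitochondrial ribosomal RNA left out, a gene length or GC trend removed by a lowess offset per library (span 0.3), and each library left out in turn. Thinning every library to the smallest total, 4939703 counts, was added after seeing the data. Some settings planned for the gene calls were applied to the lists and to CHD4 only after seeing the data: fits without robust estimation, no low-count filter, mitochondrial ribosomal RNA left out and the GC trend removed, and for CHD4 also the 5 CPM filter, the test against a fold of 1.5 and the length trend removed. GC content was known for 98.1% of tested genes. Tables were prepared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.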

Results

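The data were gene-level RNA-seq counts from THP-1, a cell line of childhood acute myeloid leukaemia with monocytic features. The cells had been transduced with lentiviral vectors. In 3 libraries the vector carried an shRNA against CHD4, and 3 libraries came from cells with negative control vectors. RNA was taken 72 h after transduction. The total count per library was 9838039, 4939703 and 10436467 in CHD4 shRNA replicates 1, 2 and 3. It was 16468551, 16511250 and 8722766 in control replicates 1, 2 and 3. The mitochondrial ribosomal RNAs took 26.7%, 23.3% and 20.4% of the counts in the knockdown libraries and 17.1%, 17.1% and 21.1% in the control libraries. The exact Clopper-Pearson 95% interval of each share reached at most 0.0373 percentage points to either side. Such intervals cover counting error only. The log2 CPM of replicates of a group correlated across genes with r between 0.984 and 0.995, where genes are not independent replicates. The first principal component held 73.9% of the variance and separated the 3 knockdown from the 3 control libraries.

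The comparison asked which transcripts differed in THP-1 cells after knockdown of CHD4, the ATPase of the nucleosome remodelling and deacetylase complex NuRD. CHD4 itself (Entrez 1108; chromosome 12, 6570082 to 6607433 on the minus strand in the coordinates of the deposited table, whose genome build is not named) fell from 429 ± 55.4 CPM in control to 47.2 ± 2.33 CPM in knockdown libraries (SD, n = 3 each). Its log2 fold change was -3.18 ± 0.0959 (SE), 9.07-fold lower, with an adjusted p of 4.17e-17 in edgeR's quasi-likelihood test. The 3 knockdown libraries held 45.8, 46.0 and 49.9 CPM and the control libraries 456, 466 and 366 CPM, so no library went against its label. The oncogene MYC (Entrez 4609; chromosome 8, 127736069 to 127741434 on the plus strand in the same coordinates) fell from 380 ± 40.0 to 216 ± 31.3 CPM (SD, n = 3 each). Its log2 fold change was -0.82 ± 0.0947 (SE), with an adjusted p of 3.95e-07 by edgeR.

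Other NuRD subunits moved in both directions. Of 14 measured genes, 5 rose, 6 fell and 3 did not pass the test. Adjusted over the list alone, 5 rose and 8 fell. The rises were CHD5, a CHD4 paralogue (2.55 ± 0.319), GATAD2B (1.21 ± 0.365), CDK2AP1 (0.72 ± 0.0968), MBD2 (0.56 ± 0.0897) and MTA3 (0.45 ± 0.131), each as log2 fold change ± SE. CHD5 and GATAD2B had low values, 6.76 and 2.55 CPM in the knockdown group. The deposited coordinates place GATAD2B on several sequences. How reads that map to more than one place were counted is not given in the sources used here, so its count is uncertain. The falls were MBD3 (-0.55 ± 0.135), MTA2 (-0.45 ± 0.0799), MTA1 (-0.40 ± 0.0714) and the deacetylases HDAC1 (-0.33 ± 0.0881) and HDAC2 (-0.22 ± 0.0715), with GATAD2A at -0.18 ± 0.0738. MBD3 did not separate the groups in every library, with 39.8 CPM in knockdown replicate 3 and 39.1 CPM in control replicate 3. RBBP7 (-0.24 ± 0.106), RBBP4 (-0.17 ± 0.0769) and CHD3 (-0.03 ± 0.0850) were not past the threshold over all genes. As a set the subunits did not stand apart from other genes (camera, adjusted p = 0.912). Their median was -0.18, their mean 0.21 and camera's direction lower. The calls of 3 subunits were lost when a library was left out. GATAD2B was not past the threshold without control replicate 2 (0.93, adjusted p = 0.0636), nor HDAC2 without control replicate 1 (-0.22). GATAD2A was not past the threshold without knockdown replicate 2 (-0.14), knockdown replicate 3 (-0.18) or control replicate 1 (-0.17), stood at -0.03 with the GC trend removed, and lost its call in 8 settings in all. CHD5 was at 3.40 without control replicate 2. MTA3 was not past the threshold on total counts (0.33) or with the gene length trend removed (0.30). In the other direction, RBBP4 passed as lower in 8 settings and RBBP7 in 6, and CHD3 passed as lower (-0.21) with the gene length trend removed.

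**Figure D1:**
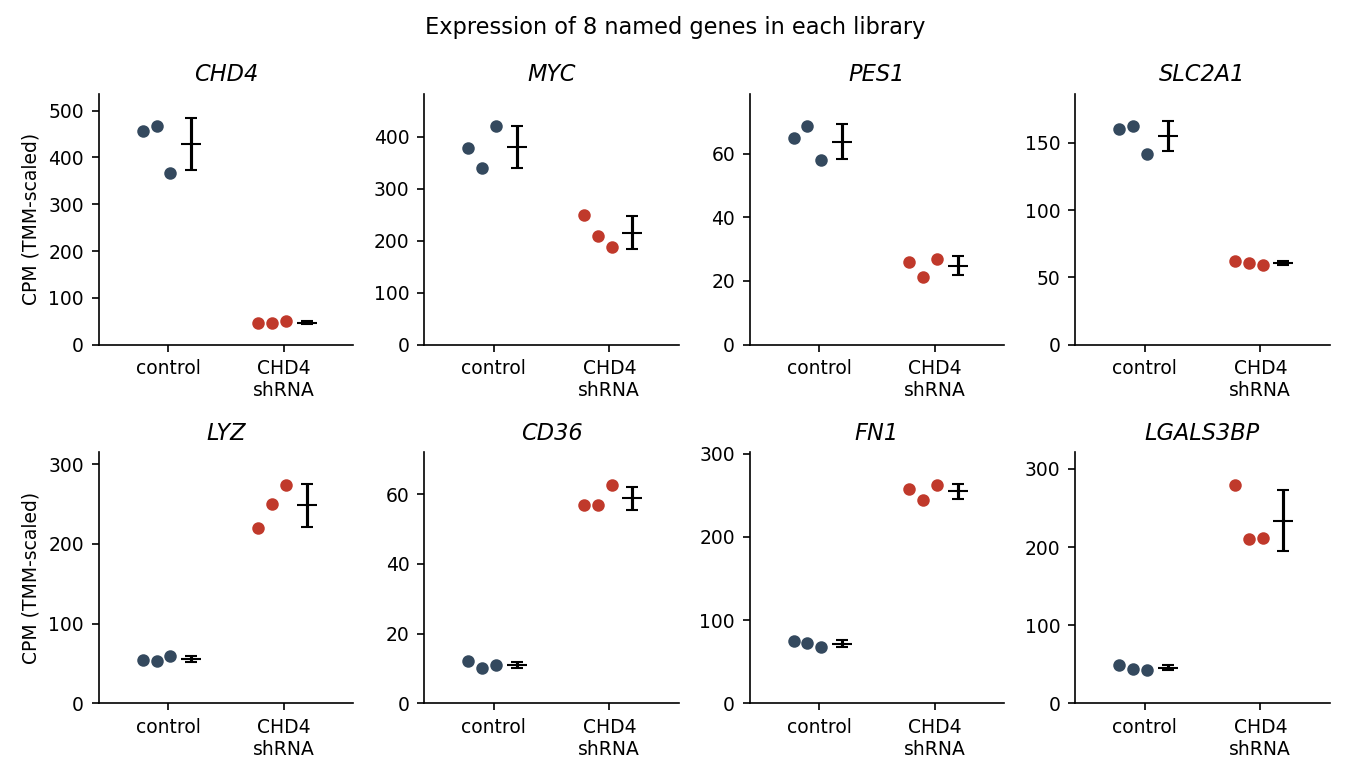
TMM-scaled CPM (y axis, linear from 0) of 8 genes in each library, with control libraries in dark grey and CHD4 shRNA libraries in red. Points are single libraries and the bar beside them is the mean ± SD over 3 libraries. CHD4 fell from 429 to 47.2 CPM, and the groups did not overlap in any of the 8 genes.

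In all, 12328 genes were tested and 6751 (54.8%) differed between the groups by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 3474 were higher and 3277 lower after CHD4 shRNA. Changes of over 2-fold were more often rises, with 970 genes higher and 380 lower. Many were small, and 3253 of the called genes (48.2%) changed by less than 1.5-fold. The knockdown and control libraries did not overlap in 7344 genes (59.6%), where chance gives 10%. Tested against a fold of 1.5, 1551 genes passed, 1043 higher and 508 lower. With libraries scaled by total count, 2600 genes were higher and 4088 lower, so that rises made up 38.9% of the calls in place of 51.5%. That scaling moved the log2 fold changes of all genes by a median of -0.12.

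The largest rises among genes with at least 5 CPM were in transcripts that were scarce in control cells, at 1.58 CPM or less. VSIG4 (Entrez 11326, chromosome X), a complement receptor of tissue macrophages, had 518 counts over the 3 knockdown libraries and 2 over the 3 control libraries. That is a depth-scaled ratio of 468, with a 95% counting interval of 129 to 3879. CREB3L3 (Entrez 84699, chromosome 19), a membrane-bound transcription factor best known from liver, rose from 0.743 ± 0.249 to 47.4 ± 2.59 CPM (SD, n = 3 each), a log2 fold change of 5.88 ± 0.172 (SE). IGLON5 (Entrez 402665, chromosome 19), a neural cell adhesion protein, rose by 5.18 ± 0.161. INS-IGF2 (Entrez 723961, chromosome 11) rose by 4.75 ± 0.212, but it shares exon sequence with IGF2 and with IGF2-AS, so its count is uncertain. STYXL2 (Entrez 92235, chromosome 1) rose by 4.60 ± 0.245 and S100A1 (Entrez 6271, chromosome 1), a calcium-binding protein of muscle, by 4.43 ± 0.215. PALLD (Entrez 23022, chromosome 4), which organises actin, rose by 3.90 ± 0.186 and the cytokine receptor IL17RE (Entrez 132014, chromosome 3) by 3.68 ± 0.178. Adjusted p-values of these 8 genes were at most 8.88e-13 (edgeR).

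The largest falls after CHD4 itself were in WWC1 (Entrez 23286, chromosome 5), a scaffold of Hippo signalling, at -2.28 ± 0.181, and HSD17B12 (Entrez 51144, chromosome 11), an enzyme of fatty acid elongation, at -2.22 ± 0.101. HSD17B12 went from 118 ± 10.3 to 25.7 ± 3.31 CPM (SD, n = 3 each). POLR3G (Entrez 10622, chromosome 5), a subunit of RNA polymerase III, fell by 1.98 ± 0.195. STX10 (Entrez 8677, chromosome 19), a SNARE of the Golgi, fell by 1.92 ± 0.208. PLAC8 (Entrez 51316, chromosome 4) was the most abundant of these after CHD4, and fell by 1.90 ± 0.0864 from 250 ± 25.5 to 66.9 ± 4.28 CPM. The adaptor subunit AP1S3 (Entrez 130340, chromosome 2) and the proton pump subunit ATP6V0E2 (Entrez 155066, chromosome 7) each fell by 1.89, with SEs of 0.118 and 0.188. Adjusted p-values were at most 8.44e-08 (edgeR). ATP6V0E2 overlaps its antisense gene, and S100A1 overlaps S100A13 on the opposite strand by 4 exon bases. Whether strand was used in counting is not given in the sources used here, so their counts are uncertain. Among genes named from the lists, MYBBP1A, TYMS, ENO1, SLC2A1, FDPS, JMJD1C, FANCI, RBBP4, NCAM1 and ZP3 also share exon bases with a gene on the opposite strand, and RBBP8 with a microRNA gene on its own strand.

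**Figure D2:**
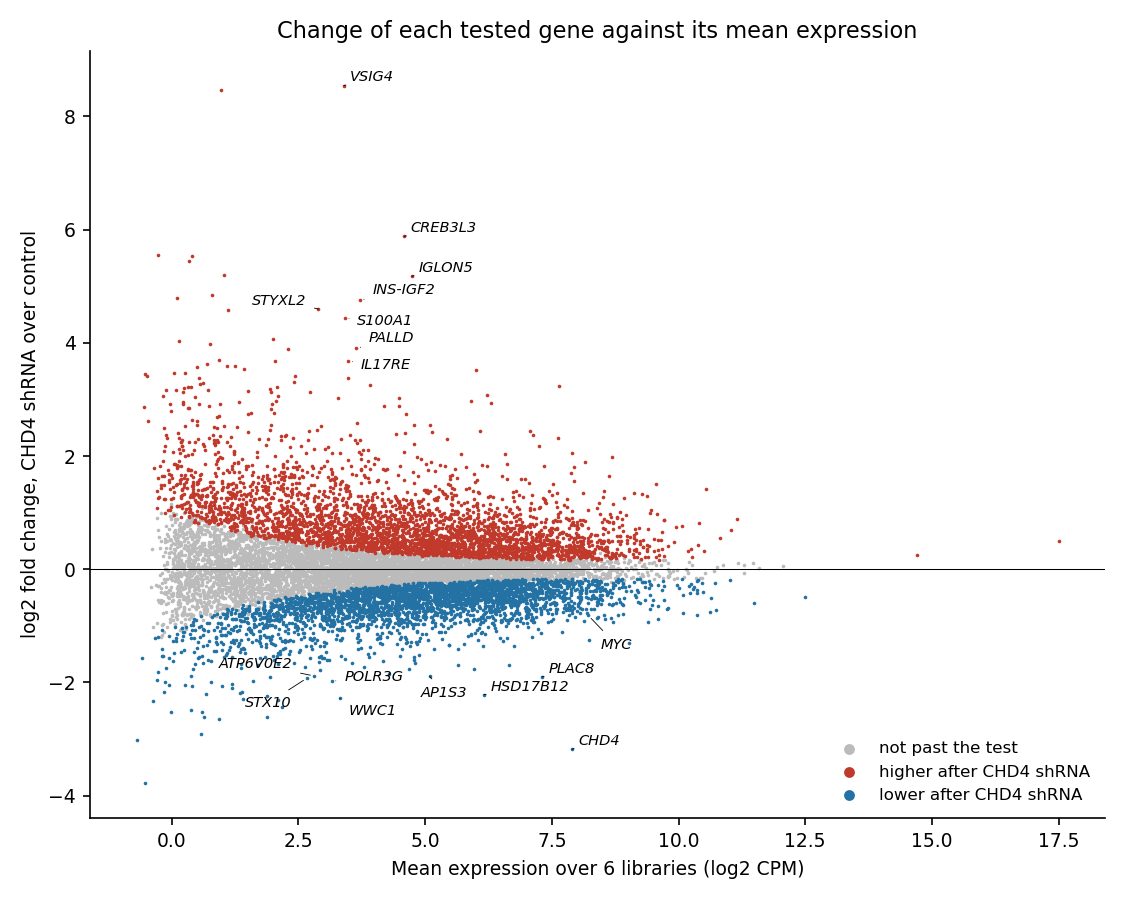
Log2 fold change of each tested gene (y axis, CHD4 shRNA over control) against its mean expression over 6 libraries (x axis, log2 CPM). Red points rose and blue points fell past the adjusted threshold, grey points did not pass, and labels name CHD4, MYC and the 8 largest rises and 8 largest falls chosen by rule. VSIG4 is drawn at its fitted value, which rests on 2 control counts. CHD4 lies at -3.18.

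Most targets of MYC fell. Of 57 measured genes, 49 fell and 1 rose, with a median log2 fold change of -0.71. MYC itself was on the list and is among the 57 and the 49. PES1 and MYBBP1A, both nucleolar proteins of ribosome production, fell by 1.35 ± 0.104 and 1.21 ± 0.0824 (SE). The 1 gene that rose was CBX3, a heterochromatin protein, named after its value was seen. The list stood below other genes by camera with a preset correlation (adjusted p = 9.44e-15), and with an estimated correlation the adjusted p was 0.0566. DNA replication and G1/S genes also fell, 35 of 56 against 2 that rose (E2F8 and RAD51AP1, named after their values were seen), with a median of -0.33. TYMS, which makes thymidylate, fell by 0.89 ± 0.0789, and MCM2, of the replicative helicase, by 0.77 ± 0.0830. The list passed camera (adjusted p = 7.52e-06; adjusted p = 0.0566 with an estimated correlation). Mitosis and G2/M genes went both ways. Of 53 genes, 13 rose and 14 fell (12 and 14 adjusted over the list alone), RANGAP1 by -0.83 ± 0.102 and TACC3 by -0.72 ± 0.0915, and the list did not stand apart (camera, adjusted p = 0.675). For all other lists below, counts adjusted over the list alone equalled those over all genes unless both are given.

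Ribosomal protein genes fell in 34 of 72 cases and rose in 3 (RPL22, RPL35A and RPS29, named after their values were seen), with a median of -0.24. RPL19 fell by 0.67 ± 0.0809 and RPL3 by 0.69 ± 0.0845. Nuclear genes of the respiratory chain fell in 18 of 45 cases and rose in 3 (SDHD, NDUFB5 and NDUFA10, named after their values were seen), with a median of -0.30. ATP5F1B, of the ATP synthase, fell by 0.79 ± 0.0733, and NDUFV1, of complex I, by 0.93 ± 0.117. Both lists passed camera, with adjusted p of 0.0021 for ribosomal proteins and 0.00826 for the respiratory chain, and with an estimated correlation the adjusted p was 0.368 for each. Log2 fold changes also followed gene length and GC content across genes (Spearman 0.19 and -0.27). With the gene length trend removed, the medians were -0.12 and -0.13 and neither list passed (adjusted p = 0.218 and 0.164). Ribosomal protein genes have many processed pseudogenes that can share their reads. Of the mitochondrial genome only the ribosomal RNAs RNR1 and RNR2 were in the table. They were higher, at 0.25 ± 0.0742 and 0.50 ± 0.161, but RNR2 did not separate the groups in every library and was at 0.34 without knockdown replicate 1 (adjusted p = 0.0704). RNR1 was at 0.13 on total counts, not past the threshold.

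Glycolysis and hypoxia genes fell in 17 of 30 cases and rose in 3 (BNIP3L, PFKFB4 and NDRG1, named after their values were seen), with a median of -0.37. The glucose transporter SLC2A1 fell from 155 to 60.6 CPM (n = 3 each), a log2 fold change of -1.36 ± 0.0802 (SE), and the glycolytic enzyme ENO1 by 0.93 ± 0.0784. The list passed camera (adjusted p = 0.000127; adjusted p = 0.0566 with an estimated correlation). In cholesterol synthesis, 9 of 24 genes fell, led by INSIG1 (-1.22 ± 0.130) and FDPS (-0.79 ± 0.125), and 4 rose (among them HMGCS1, STARD4 and HSD17B7, named after their values were seen). As a set they missed the threshold (adjusted p = 0.113). In the unfolded protein and ATF4 response, 17 of 39 genes fell and 8 rose, or 17 and 9 adjusted over the list alone. TRIB3 fell by 1.32 ± 0.122 and the amino acid transporter SLC7A5 by 1.30 ± 0.0840, from 740 ± 38.6 to 301 ± 38.5 CPM (SD, n = 3 each). The list did not pass (adjusted p = 0.238).

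Monocyte and macrophage markers rose. Of 37 measured genes, 24 rose and 5 fell, with a median of 0.67. LYZ, the lysozyme gene, rose from 55.2 ± 3.68 to 248 ± 27.1 CPM (SD, n = 3 each), a log2 fold change of 2.17 ± 0.0872, and the scavenger receptor CD36 by 2.42 ± 0.107. Among those that fell were the chemokine receptors CCR2 and CX3CR1, the receptor CSF1R and the calcium-binding protein S100A9, named after their values were seen. S100A9 fell by 1.18 and CSF1R by 0.23. The list passed camera (adjusted p = 1.52e-07; adjusted p = 0.0566 with an estimated correlation). Only 8 neutrophil granule genes were measured. Of these, 5 fell and 1 rose (CSF3R, named after its value was seen), with SERPINB10 at -1.39 ± 0.162 and the protease gene CTSG at -0.91 ± 0.0857. That list missed the threshold (adjusted p = 0.0619) and passed it without control replicate 2 (adjusted p = 0.0351), on total counts (0.0497) and by fry (0.00189).

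**Figure D3:**
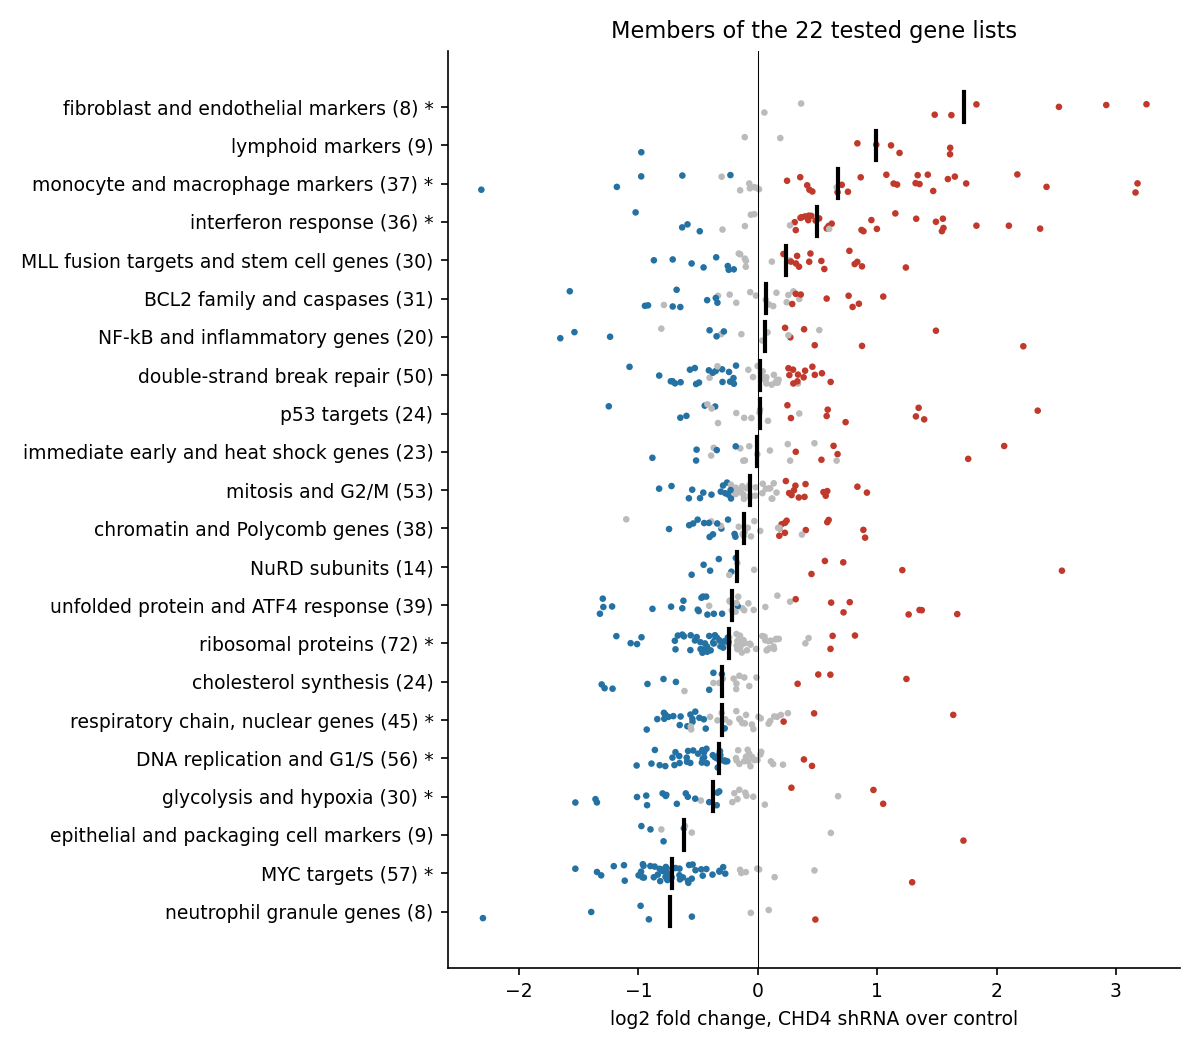
Log2 fold changes (x axis, CHD4 shRNA over control) of the measured members of 22 gene lists, with the number measured in parentheses. Red points rose and blue points fell past the adjusted threshold over all genes, grey points did not pass, black bars are list medians, and vertical scatter within a list has no meaning. Asterisks mark the 8 lists past camera's adjusted threshold of 0.05 with the preset correlation. The median of the MYC targets was -0.71 and that of the monocyte and macrophage markers 0.67.

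Among MLL fusion targets and stem cell genes, a class tied to the MLL fusion that THP-1 cells carry, 14 of 30 rose and 8 fell (14 and 9 adjusted over the list alone). JMJD1C rose from 592 ± 12.5 to 1084 ± 30.9 CPM (SD, n = 3 each), a log2 fold change of 0.87 ± 0.0680, and CPEB2 by 1.24 ± 0.0924. HOXA9 (-0.10 ± 0.243) and HOXA10 (-0.10 ± 0.109), and MYB (-0.15 ± 0.0752), named after their values were seen, were not past the threshold. The list did not stand apart (camera, adjusted p = 0.238), and passed by fry (adjusted p = 0.00856), which does not compare it with other genes. Interferon response genes rose in 26 of 36 cases and fell in 4 (EIF2AK2, IFITM2, IFIH1 and USP18, named after their values were seen), with a median of 0.50. LGALS3BP rose by 2.36 ± 0.101 and SAMD9L by 1.83 ± 0.105. The list passed camera (adjusted p = 1.47e-05; adjusted p = 0.0964 with an estimated correlation). NF-kB and inflammatory genes went both ways, 7 of 20 up and 6 down, with the adhesion molecule ICAM1 at 1.49 ± 0.160 and the chemokine CXCL8 at 2.22 ± 0.384. CXCL8 was scarce, at 2.90 CPM in the knockdown group. This list did not pass (adjusted p = 0.830), with a median of 0.06 and camera's direction lower. Immediate early and heat shock genes were also divided, with 6 of 23 up and 5 down (HSP90AA1, HSPA8, HSPH1, DNAJB1 and IER2, named after their values were seen). KLF2 rose by 1.76 ± 0.144 and EGR3 by 2.06 ± 0.333. EGR3 was also scarce, at 3.05 CPM in the knockdown group. The list did not pass (adjusted p = 0.914), with a median of -0.0032, a mean of 0.18 and camera's direction higher.

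Lists of cell death and DNA damage did not stand apart from other genes. Of 24 p53 targets, 9 rose and 5 fell (MDM2, POLH, AEN, TIGAR and TNFRSF10B, named after their values were seen). TP53INP1 rose by 2.34 ± 0.233 and CCNG1 by 0.74 ± 0.0851. CDKN1A, the cell cycle inhibitor induced by p53, was at 0.02 ± 0.122 and not past the threshold, and is also named after its value was seen. The adjusted p of the list was 0.675 by camera and 0.0273 by fry. Of 31 genes of the BCL2 family and caspases, 8 rose and 9 fell. The death receptor TNFRSF10A fell by 1.57 ± 0.265 and the survival gene BCL2 by 0.71 ± 0.0826. That list had a median of 0.07, a mean of -0.05 and an adjusted p of 0.912, with camera's direction higher. Of 50 genes of double-strand break repair, 12 rose and 20 fell (12 and 21 adjusted over the list alone), FANCI by -0.73 ± 0.0731 and RBBP8 by -0.69 ± 0.0801. The median was 0.02, the mean -0.08, camera's direction lower and the adjusted p 0.353. Of 38 other chromatin and Polycomb genes, 11 rose and 13 fell, with SMARCA4 at -0.57 ± 0.0809 and the demethylase KDM1A at -0.54 ± 0.0770 (list adjusted p = 0.675).

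Markers of cell types other than the monocytic lineage moved in different directions. The low-count filter kept 8 of 22 matched fibroblast and endothelial markers, 9 of 36 lymphoid and 9 of 26 epithelial and packaging cell markers. It kept 4 of 30 erythroid and megakaryocyte markers and 2 of 35 germline genes, and the results cover only the genes kept. Of 8 measured fibroblast and endothelial markers, 6 rose. The other markers, PECAM1 and S100A4, named after their values were seen, were not past the threshold. The median was 1.73. FN1, the fibronectin gene, rose from 71.4 ± 3.95 to 255 ± 9.45 CPM (SD, n = 3 each), a log2 fold change of 1.83 ± 0.0754, and the collagen gene COL1A1 rose by 3.26 ± 0.155 to 27.2 ± 2.74 CPM. The list passed camera (adjusted p = 2.37e-07; adjusted p = 0.0566 with an estimated correlation). COL1A2, named after its value was seen, encodes the partner chain of COL1A1 in type I collagen. It had 0 counts in the 3 knockdown libraries, which allows up to 0.124 CPM. Of 9 lymphoid markers, 6 rose and 1 fell (PAX5, named after its value was seen), with TCF7 at 1.19 ± 0.103 and NCAM1 at 1.61 ± 0.167 (list adjusted p = 0.143). Of 9 epithelial and packaging cell markers, 4 fell and 1 rose (MUC1, named after its value was seen), with LIN28B at -0.97 ± 0.0885 and NEFH at -0.90 ± 0.102 (list adjusted p = 0.263). Of 4 erythroid and megakaryocyte markers, ITGA2B rose by 3.13 ± 0.266 and NFE2 was at -0.56 ± 0.125, both past the threshold. Of 2 germline genes, ZP3 fell by 1.21 ± 0.385. It was scarce, at 1.81 CPM in the control group and 0.807 CPM in the knockdown group. ZP3 was not past the threshold without knockdown replicate 3 (-0.95) or control replicate 1 (-1.03). Those last lists had too few measured genes for a set test.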

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

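Thinning the libraries was chosen after seeing the data. So was applying fits without robust estimation, no low-count filter, no mitochondrial ribosomal RNA or no GC trend to the lists and CHD4, and for CHD4 also the 5 CPM filter, the fold of 1.5 and no length trend. The other alternatives were chosen before. CHD4 stayed lower and past the threshold under all alternatives run, between -3.30 and -3.12 with each library left out in turn. The number of called genes was 6751. It lay between 5755 and 7004 without each library in turn, and was 6044 with DESeq2, 6783 with limma-voom, 5246 at a threshold of 0.01 and 5634 with libraries thinned to the smallest. Of the 6751 genes, 81.5% were also called with the GC trend removed, where 129 changed sign. That fit tested only the 12096 genes with known GC content, and called genes without it count as lost in this share. Tested against a fold of 1.5, 1551 genes passed, 1043 higher and 508 lower, since that test asks for a larger change. Total-count scaling gave 2600 higher and 4088 lower, with a median shift of -0.12. On that scale the medians of the p53 (-0.11), break repair (-0.11), NF-kB (-0.06) and BCL2 (-0.06) lists fell below 0. The replicate number as a block gave 6409 genes (3319 higher, 3090 lower) and added the neutrophil list (adjusted p = 0.0479). Libraries of the same number did not deviate together (correlations 0.02, -0.07 and -0.04), and not every library correlated best with its own number. These values show no sign of pairing by number, but 3 libraries per group are too few to exclude it. Of the lists, 3 were higher and 5 lower by camera. An estimated correlation left 0 higher and 0 lower. The estimate lay below the preset 0.01 for the glycolysis (0.0072) and fibroblast (0.0087) lists. A higher correlation therefore cannot account for the change in those lists. The adjusted p-values with an estimated correlation thus cannot be read as an effect of gene correlation alone. For the other lists that had passed, the estimate lay between 0.0122 and 0.0894. Fry, which does not compare a list with other genes, called 6 higher and 9 lower. The cause of these changes was not tested further. With the gene length trend removed 3 were lower. The cholesterol list passed without a low-count filter (adjusted p = 0.0470). The results that reversed were not past the threshold in either setting. CHD3 was at 0.12 with the GC trend removed and between -0.12 and 0.044 without each library in turn. Camera's direction turned for NuRD (median -0.13) and NF-kB (0.16) with the GC trend removed, for BCL2 (-0.069) without a low-count filter and for immediate early genes (-0.020) at a mean of 5 CPM. Without each library in turn, the medians of the BCL2 list lay between -0.033 and 0.069 and those of the immediate early list between -0.079 and 0.079. By fry NuRD was higher (median -0.18). The cause was not tested for these reversals. Over all alternatives, named genes other than CHD4 gave 1466 values with the same direction and side of the threshold, 41 that lost the call, 15 that gained it and 3 that reversed. Depth limits both the genes tested and the calls, since with libraries thinned to the smallest 11156 genes were tested in place of 12328 and 5634 called in place of 6751.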

Other observations

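The tests of symbol roots, matched random lists, thinned libraries, fibroblast transcripts and neighbouring genes were chosen after the results were seen, as was the use of the GC and length corrections to weigh the lists. Genes were grouped by a shared symbol root with at least 8 measured members, which can take in antisense genes and pseudogenes of the same root. Of 194 roots tested with camera, 12 passed at an adjusted p under 0.05 with the preset correlation. With an estimated correlation 0 passed (adjusted p = 0.926 for each), and 5 had an unadjusted p under 0.05. The EIF root, which holds translation initiation factors, their kinases and binding proteins, had 32 of 53 genes lower and 5 higher, with a median of -0.32. The helicase roots DDX and DHX had 21 of 34 and 11 of 15 genes lower, with medians of -0.31 and -0.30. The POLR root of RNA polymerase genes had 17 of 32 lower and 4 higher, among them POLR1G and POLR2I at -1.47 and -1.40. Genes of these roots named here were chosen after their values were seen. The roots CCT (7 of 9 genes lower), NUP (13 of 22), IPO (6 of 10), MCM (8 of 11), RRP (6 of 9) and NOP (5 of 9) were lower as well with the preset correlation. These overlap in part with the MYC target and replication lists.

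The roots that were higher by camera with the preset correlation were KLF and COL (adjusted p = 0.926 for each with an estimated correlation). Of 15 genes with the KLF root, mostly zinc finger transcription factors, 10 rose and 1 fell, with KLF2 at 1.76, KLF10 at 1.07 and KLF7 at 1.04, and KLF16 at -0.76. Of 18 genes with the COL root, 9 rose and 3 fell, with COL1A1 at 3.26, COL6A3 at 2.92 and COL24A1 at 2.74. Those that fell were COL15A1 (-0.63), COL8A2 (-0.47) and COL4A1 (-0.43). COL1A1 and COL6A3 are also on the fibroblast and endothelial list. Genes given from these roots, other than KLF2 and COL1A1, were named after their values were seen. HSD17B12 and API5, both on chromosome 11, were among the strongly lower genes, at -2.22 and -1.77, while TTC17 (0.18) and ALKBH3 (-0.02) were not past the threshold. API5, TTC17 and ALKBH3 were named after their values were seen.

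MYC targets (a list with MYC itself on it), replication genes and glycolysis genes were lower as lists by camera with the preset correlation (adjusted p = 0.0566 for each with an estimated correlation), while fold changes of all genes followed GC content, from a median of 0.37 in the tenth lowest in GC to -0.18 in the highest. The largest adjusted p of the 3 lists by camera was 0.00121 with the GC trend removed, 0.000165 with the length trend removed and 0.000185 with libraries thinned to the smallest total, which argues against these as the whole cause. Whether the fall in MYC (-0.82) contributes was not tested, and restoring MYC in knockdown cells would test it. The ribosomal protein and respiratory chain lists differed, since with the length trend removed their smaller adjusted p was 0.164 and medians went from -0.24 to -0.12 and from -0.30 to -0.13. Among random lists of matched length, 9.56% and 4.90% lay as low, so a length trend may account for much of their fall, while with the GC trend removed both passed at the preset correlation (largest adjusted p = 0.0274), though neither passed with an estimated correlation and no trend removed (adjusted p = 0.368 for each).

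Fibroblast and endothelial markers were higher, with COL1A1 at 652 counts in the knockdown libraries against 124 in the control libraries. Fibroblasts among the knockdown cells would bring their other abundant transcripts, but COL1A2, COL3A1, DCN and LUM together had 0 counts in the 3 knockdown libraries, which allows up to 0.124 CPM against 26.9 CPM for COL1A1. That argues against such cells as the source, and the list also stayed past camera's threshold with the GC or length trend removed and in thinned libraries, but not with an estimated correlation (adjusted p = 0.0566). Whether the THP-1 cells themselves carried these transcripts was not tested, and RNA-seq of single cells would test it. Of the 8 measured markers, PECAM1, at 268 CPM in control cells, and FN1, at 71.4 CPM, were already expressed in THP-1.

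Neighbouring genes changed together to a small extent. Over 8030 pairs of adjacent tested genes more than 5 kb apart and with different symbol roots, the Spearman correlation of log2 fold changes was 0.0918 across genes, which are not independent replicates. It lay above all 1000 shuffled orders (highest 0.0535; permutation p = 0.001, the smallest that 1000 shuffles can give). With the GC trend removed it was 0.0309 (permutation p = 0.009), below the highest shuffled value of 0.0366. A part of it may come from GC content shared by neighbours, and position along the chromosome cannot be told apart from GC content here, since the remainder is small and the correction also removes changes that track GC for other reasons.

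The number of genes that differed between the groups, 6751, was reached by 1 of the 10 splits of the 6 libraries into 3 and 3, the real one. The highest of the other splits was 0 genes by edgeR at the adjusted threshold, with between 29 and 232 genes at an unadjusted p under 0.05. No other tool was run on the splits. Each of the other splits mixes knockdown and control libraries, so the difference between the groups adds to the spread within each side. Few calls in those splits were thus built into the design, and nothing is concluded from the 0. With 10 splits the share is never under 0.1, too few for a share under 0.05.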
